A study of Homo sapiens with 6 samples.

How the data were processed

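P493-6 is a human B-cell lymphoma line in which a c-Myc transgene is held off by tetracycline. RNA was measured on 1-colour Affymetrix arrays in 3 groups of 2 arrays: low-Myc (c-Myc released for 0 hours), mid-Myc (1 hour) and high-Myc (24 hours). For the mid-Myc samples one protocol field of the labels gives 0 hours and another 1 hour, and the second was used because the group is described as expressing a moderate level. The design text calls the arrays biological duplicates. The sample numbers of the mid-Myc arrays do not follow on from those of the other groups, so these arrays may have been made separately. If so, a batch difference could not be told apart from a change at 1 hour. ERCC synthetic RNAs were added by cell number before labelling, per the labels' protocols.

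The deposited values are probe set intensities on a linear scale, summarised by the authors with MAS5 per the submitters' processing notes. The version and the target of its scaling are not given in the sources used here. The table held 49495 probe sets, of which 49293 were human, 100 were ERCC and 102 were other controls. Of the human probe sets, 45278 carried 1 gene symbol, 1333 several and 2682 no listed symbol, and only those with 1 symbol were named. Symbols were updated through Entrez identifiers, which were found in the gene table for 45208 of the probe sets with 1 symbol. The table holds no detection calls, so dim values include background signal, which can move with the groups. The number of arrays limits the precision.

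Values were analysed as log2 on 2 scales. On the per-cell scale, a robust loess curve (span 0.7, degree 1) through the ERCC probe sets of each array, against their mean over the 6 arrays, was subtracted from every probe set. This scale was used because the ERCC probe sets were not level in the deposited values. On the equal-median scale, each array was centred on the median of its human probe sets, which takes the total RNA per cell as equal. Each gene was represented by its probe set with the highest mean, and was tested if that mean was above the 40th percentile of the human probe sets (33.8 intensity), which left 12198 genes. Of these, 9076 had further probe sets, which were not averaged. Among named and listed genes with further probe sets above the filter, all of them had the sign of the one used per cell for 102 of 114 genes in high-Myc against low-Myc, 93 of 105 in mid-Myc against low-Myc and 101 of 113 in high-Myc against mid-Myc, and on the equal-median scale for 108, 80 and 103. Differences were tested with limma (version 3.58.1, R 4.3.3) in 1 fit over the 6 arrays with a variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors given as SE come from that fit. An exact permutation test of 2 arrays against 2 cannot give a p below 0.33.

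The 39 gene lists were tested against all other genes with camera (correlation 0.01) on the equal-median scale. Alternatives were camera with an estimated correlation, fry on the per-cell scale, and the percentile of a list's median among 10000 random lists matched on expression level. With an estimated correlation, camera takes its degrees of freedom from 6 arrays in 3 groups, which leaves it little power. A call missed there therefore decides little. Fry tests a list against no change and not against other genes. The groups, the tests, the gene lists, the rule for named genes and the use of a loess curve where the ERCC probe sets were not level were fixed before the data were examined. The span, the degree and the robust fit of that curve were chosen after the ERCC values had been seen. Named genes were MYC, then among called genes whose arrays did not overlap between the groups, the 10 with the largest rise and the 10 with the largest fall on the per-cell scale (5 and 5 for high-Myc against mid-Myc), and up to 4 members per list with the largest change on the equal-median scale.

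The steps were tested on simulated data with 12198 genes. On the equal-median scale, 94% of genes changed by 0.5 log2 were recovered for high-Myc against low-Myc, 92% for mid-Myc against low-Myc and 91% for high-Myc against mid-Myc, and 100% of those changed by 1 log2 in each. For each size 100 genes were changed, up and down alike, far fewer than were called in the data. Per-cell changes simulated for high-Myc against low-Myc had a median error of -0.069 log2. In 20 draws with no change, the per-cell steps called at most 2 genes for high-Myc against low-Myc. These draws held independent noise per probe set and no error in cell number or added RNA, so they do not test such an error. Alternatives covered the filter, the choice of probe set, a pseudocount of 16, the variance trend, the replicate number as a block, the groups in the fit, each array left out in turn and other scalings. The span of 0.4, the curve through the brighter ERCC probe sets, the curve read at each array's own level, the centring on tested genes, cyclic loess, the 80th percentile filter, the level-matched lists and the counts of list members under each centring were chosen after seeing the data.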

Results

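The data are 6 arrays of P493-6 B cells, 2 each at 0, 1 and 24 hours after c-Myc was released from repression. The question of the series, as its title and design state it, is how the reading of gene expression depends on whether arrays are scaled to an equal level or to RNA added by cell number. Within each group the replicates correlated at r = 0.996 across the tested genes on the equal-median scale, a correlation over genes and not over samples. The limma p-values of single genes below rest on the spread between duplicates, of which each group had 2. They also rest on a spread borrowed from all genes through the variance trend. With that borrowing the degrees of freedom were 9.21 per cell and 12.9 on the equal-median scale. The p-values of camera with the preset correlation and of level-matched lists rest on the spread over genes, which are not replicates.

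MYC itself, the gene whose transgene was released, was read by 1 very bright probe set. Whether that probe set reads the transgene, the cell's own MYC gene or both is not given in the sources used here. Its mean deposited intensity was 10380 in low-Myc, 9986 in mid-Myc and 11930 in high-Myc arrays. On the per-cell scale MYC was higher by 0.96 (log2, SE 0.03, limma adjusted p = 4.16e-10) at 24 hours and by 0.13 (SE 0.03, adjusted p = 0.00282) at 1 hour. With arrays centred on an equal median it was higher by 0.34 (adjusted p = 2.68e-07) and 0.095 (adjusted p = 0.0339). The 24-hour value was 0.18 with quantile normalization, 0.19 with cyclic loess, 0.14 centred on the tested genes and 0.20 as deposited, and 1.45 per cell with one factor per array. From 1 to 24 hours MYC was higher by 0.84 per cell (adjusted p = 1.82e-09). The direction of the 1-hour value was not settled, since MYC was at -0.055 in the values as deposited, -0.15 with quantile normalization, -0.020 when centred on the tested genes and -0.16 with cyclic loess, against 0.31 per cell with one factor per array. The MYC values therefore do not check the mid-Myc label. Its per-cell call at 1 hour was lost with no variance trend (adjusted p = 0.0696). The equal-median call was lost with no variance trend (adjusted p = 0.293), with no filter (adjusted p = 0.0844), with log2(value + 16) (0.057, adjusted p = 0.165), and without low-Myc replicate 2 (0.074, adjusted p = 0.208), mid-Myc replicate 1 (0.11, adjusted p = 0.066) or mid-Myc replicate 2 (0.084, adjusted p = 0.145). The brightest ERCC probe sets stayed 0.084 above their curve in mid-Myc arrays.

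The ERCC synthetic RNAs, added by cell number, were dimmer in the arrays labelled mid-Myc and high-Myc than in low-Myc arrays. The 27 probe sets in the middle of the intensity range were 2.58-fold lower in high-Myc than in low-Myc arrays and 1.32-fold lower in mid-Myc arrays. The 44 dimmest probe sets were 1.19-fold lower and the 7 brightest 1.34-fold lower in high-Myc arrays, so the measured difference shrank at both ends of the range. After the curves were subtracted, the 7 brightest ERCC probe sets still lay higher than in low-Myc arrays, by a median of 0.31 (SD 0.09) in high-Myc and 0.08 (SD 0.03) in mid-Myc arrays. The 27 in the middle had medians of -0.16 (SD 0.20) and -0.03 (SD 0.15). Relative to ERCC probe sets of their own brightness, per-cell rises were therefore overstated by about these amounts in very bright genes and understated in genes of middle intensity. In high-Myc against low-Myc arrays the poly-A controls lys and phe lay at -1.05 ± 0.07 and -1.05 ± 0.05 (SD over probe sets). In the same way dap lay at -0.66 ± 0.03, thr at -0.49 ± 0.17 and the hybridization controls at -0.23 ± 0.04. The 11 brighter Tag control probe sets lay at -1.19 ± 0.25. In mid-Myc against low-Myc arrays lys and phe lay at -0.26 and -0.24 and the Tag controls at -0.34. There dap, thr and the hybridization controls each lay at 0.06. The 3' to 5' signal ratio of ACTB was 2.81 ± 0.07 in low-Myc, 2.97 ± 0.13 in mid-Myc and 3.56 ± 0.16 in high-Myc arrays (SD, n = 2), and that of GAPDH was 1.17, 1.23 and 1.17.

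**Figure D1:**
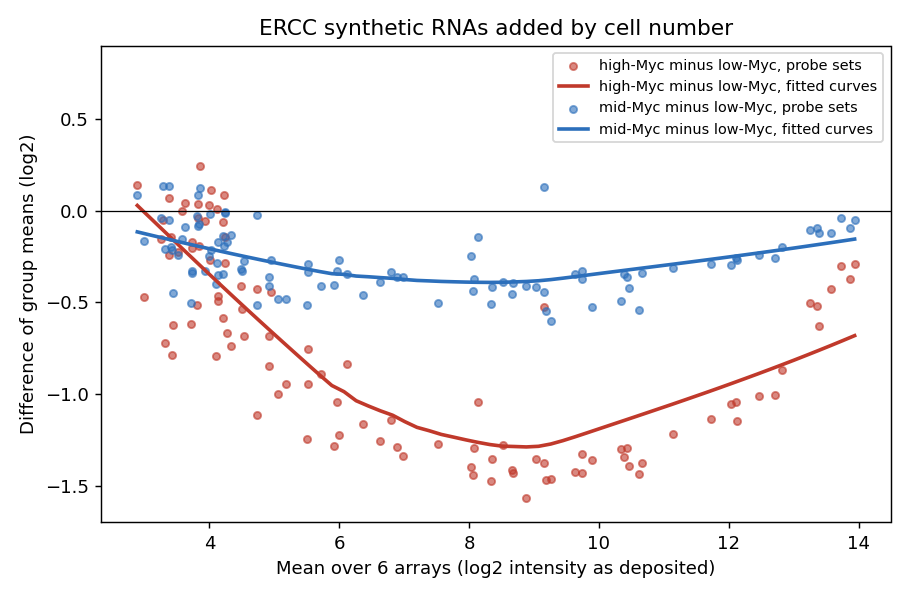
Difference between groups (log2) of each ERCC probe set against its mean log2 intensity over the 6 arrays, with the fitted curves as lines. High-Myc arrays lie below low-Myc arrays by most in the middle of the range, and the 7 brightest probe sets lie above that curve by a median of 0.31.

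Measured against the ERCC RNAs, most genes were higher in high-Myc than in low-Myc cells. The largest rises were in MTHFD1L, a mitochondrial one-carbon enzyme (4.89 log2, SE 0.07), the fatty acid binding protein FABP5 (4.59, SE 0.07), the serine synthesis enzyme PSAT1 (4.56, SE 0.06), BZW2 (4.51, SE 0.08) and ADGRA3 (4.39, SE 0.14). NOP16, PUS7, DSCC1, CHAC2 and PAICS rose by 4.35, 4.28, 4.20, 4.17 and 4.08. The largest falls were in FOS (-5.80, SE 0.06), RGS2 (-4.47, SE 0.05) and EGR1 (-4.21, SE 0.07), of which FOS and EGR1 are immediate early genes. The nuclear receptors NR4A3, NR4A1 and NR4A2 changed by -3.83, -3.44 and -2.70, although neither of the 2 other NR4A3 probe sets above the filter had that sign, and 1 of the 5 others of EGR1 did not. The activation marker CD69 changed by -3.62, RUNDC2A by -2.68, the histone gene H3-5 by -2.38 and the polyamine-degrading enzyme SAT1 by -2.14. The highest adjusted p among these 20 genes was 1.15e-05 (limma, Benjamini-Hochberg). The size and rank of several are not settled, because their dimmer side was not clearly above background: ADGRA3 was at 18.2 intensity in low-Myc arrays, and NR4A3, NR4A2 and H3-5 were at 23.8, 23.9 and 10.5 in high-Myc arrays, below the filter level of 33.8. RGS2 (35.1), FOS (38.2), CHAC2 (40.1), DSCC1 (45.6), EGR1 (46.4) and BZW2 (48.7) were close to it on their dimmer side. On that side all 20 genes lay within the intensity range of the background probe sets, which reached 694. Only 1 background probe set lay there, and the next brightest was at 194. SAT1 (424.5), PAICS (278.7), NOP16 (225.2) and FABP5 (203.2) were above 194 on their dimmer side.

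Of 12198 genes, 11077 were higher and 309 lower on the per-cell scale, 5908 and 47 of them by 2-fold or more. The median gene rose by 0.97 log2, 1.96-fold, with a range of 1.89 to 2.03 on resampling the ERCC probe sets. The median over tested genes was 6.85 and 6.88 on the low-Myc arrays and 8.13 on each high-Myc array (exact permutation p = 0.333, the smallest this design allows). These array medians differ by more than the median of the changes of single genes, which is another measure. On the equal-median scale 4598 genes were higher and 3172 lower. Of those 3172 genes, 2232 were higher per cell, 309 lower per cell and 631 not called per cell. The rise was not alike over the range: the 1220 dimmest genes, around 37.7 intensity, had a median of 0.57 and the 1220 genes around 441 intensity a median of 1.32. Dim genes cannot be separated from background, because antigenomic background probe sets, which match no transcript of these cells, lie at the same intensities. The 7 of them above the filter also rose by 0.73 to 1.56 per cell. As deposited, all 23 lay at 0.01 ± 0.09 (SD) in high-Myc against low-Myc arrays, so this rise largely restates the subtracted curve. The equal-median split depended on the centring, with 59.2% higher among the called, against 41.5% (3500 higher, 4931 lower) when centred on the tested genes and 47.2% (3741 and 4177) with quantile normalization. Centring on the tested genes moved the median change from 0.05 to -0.15.

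**Figure D2:**
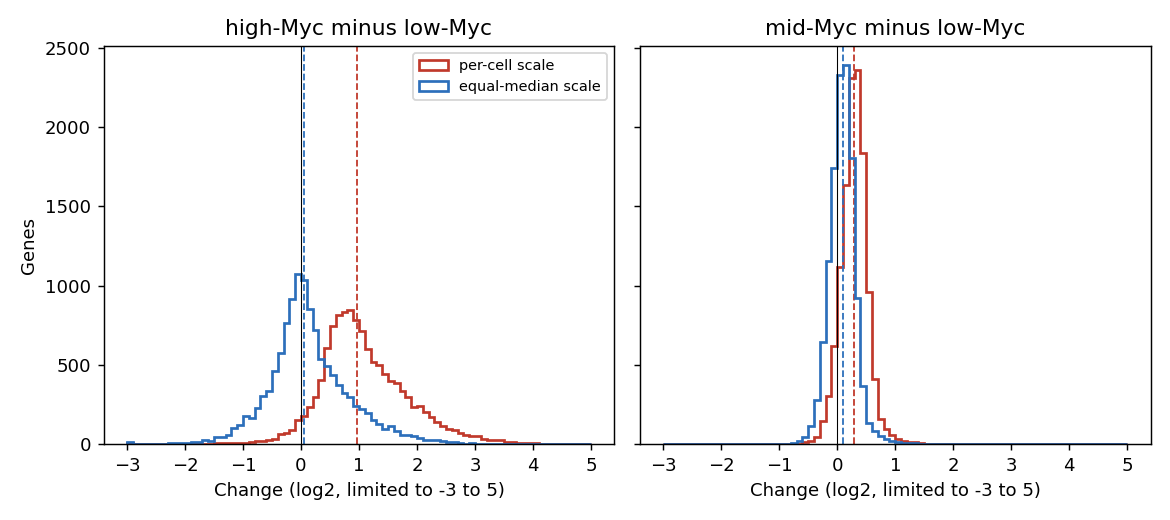
Number of genes by change (log2, limited at the ends of the axis) on each scale, for high-Myc and mid-Myc against low-Myc cells, with dashed lines at the medians. For high-Myc cells the median is 0.97 on the per-cell scale and 0.05 on the equal-median scale.

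Relative to other genes, that is on the equal-median scale, genes for making ribosomes, nucleotides and DNA were higher in high-Myc cells. All 62 measured ribosome biogenesis genes were higher (62 also adjusted over the list alone, median 1.81), among them NOP16 (3.20), LYAR (2.85), WDR12 (2.77) and RRS1 (2.71). Their camera test gave adjusted p = 1.18e-20 and adjusted p = 0.151 with an estimated correlation. No list of this comparison went below 0.151 in the latter test, which has little power with 2 arrays per group. All 32 classic MYC targets were higher (32 adjusted over the list alone, median 1.91), among them the spermidine synthase SRM (2.93), PHB1 (2.66), PA2G4 (2.64) and CAD (2.60). For these camera gave adjusted p = 3e-15 and adjusted p = 0.151 with an estimated correlation. Of 26 nucleotide synthesis genes, 25 were higher (25 adjusted over the list alone), led by the purine enzymes PAICS (2.93), PFAS (2.66) and PPAT (2.59). The test of this list gave camera adjusted p = 1.15e-11 and adjusted p = 0.151 with an estimated correlation. All 45 DNA replication genes were higher (45 adjusted over the list alone, median 1.53), with POLE2 at 2.64, CDC6 at 2.48 and MCM10 at 2.41. Also higher were 37 of 40 mitosis genes (37 adjusted over the list alone), with MAD2L1 at 2.38. Camera gave adjusted p = 3e-15 and 2.23e-08 for replication and mitosis, and each had adjusted p = 0.151 with an estimated correlation.

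Mitochondrial and protein-making genes were also higher. Of 49 genes of mitochondrial translation and import, 47 were higher (47 adjusted over the list alone), with the helicase TWNK at 2.15 and the chaperonin HSPE1 at 2.09. Among oxidative phosphorylation genes 35 of 37 were higher (35 adjusted over the list alone), with ATP5MC1 at 2.53 and cytochrome c, CYCS, at 2.27. Camera gave adjusted p = 5.35e-15 and 1.15e-11, with adjusted p = 0.151 and 0.164 with an estimated correlation. Higher too were 39 of 40 translation factors, 30 of 30 proteasome genes, 26 of 27 chaperones and 19 of 20 aminoacyl-tRNA synthetases (39, 30, 26 and 19 adjusted over the list alone), with EIF2S1 at 1.96, PSMG1 at 2.89, FKBP4 at 2.54 and FARSB at 2.27. Their camera adjusted p values were 4.99e-10, 4.47e-10, 3.96e-09 and 6.56e-07, and adjusted p = 0.157, 0.164, 0.151 and 0.198 with an estimated correlation. Cytosolic ribosomal proteins, which lie among the brightest genes, were higher in 56 of 64 (57 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 1.52e-07, and adjusted p = 0.151 with an estimated correlation), and did not stand apart from random lists of their level (adjusted p = 0.388). With quantile normalization 32 of these ribosomal protein genes were higher and 7 lower, and centred on the tested genes 23 and 16, whereas the ribosome biogenesis count was 61 of 62 under either.

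Genes of B cell identity and immune response stood below the rest in high-Myc cells. Of 31 B cell identity genes, 28 were lower (28 adjusted over the list alone), with the receptor partners CD72 (-2.16) and CD79B (-1.50), although neither of the 2 other CD79B probe sets above the filter had that sign. Likewise 36 of 37 interferon response genes were lower (36 adjusted over the list alone), with RSAD2 (-1.93), IFI27 (-1.68) and IFIT2 (-1.62). Camera gave adjusted p = 6.76e-13 and 2.3e-16, and adjusted p = 0.151 with an estimated correlation for each. Antigen presentation genes were lower in 20 of 25 (20 adjusted over the list alone), with HLA-E at -1.33. Lower too were 20 of 24 genes of CDK inhibition and quiescence (20 adjusted over the list alone), with YPEL5 at -2.51 and CDKN2D at -1.92. Camera gave adjusted p = 1.46e-08 and 5.9e-08, with adjusted p = 0.151 and 0.157 with an estimated correlation. Immediate early genes were lower in 24 of 28 (24 adjusted over the list alone, camera adjusted p = 3.89e-11, and adjusted p = 0.151 with an estimated correlation).

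The medians of these groups stayed below 0 with quantile normalization, cyclic loess and centring on the tested genes. Per cell, 19 of the 37 interferon genes and 19 of the 31 B cell identity genes were higher, and 8 and 7 were lower. Genes of CDK inhibition and quiescence were higher per cell in 15 of 24 and lower in 8. Antigen presentation genes were higher per cell in 23 of 25 and lower in 1, whereas immediate early genes were lower per cell in 14 of 28 and higher in 12. Markers of other cell types were near the floor of the arrays: of 12 T and NK cell markers, 11 were higher per cell and 3 lower on the equal-median scale (3 adjusted over the list alone, camera adjusted p = 0.076). Of 6 monocyte markers 3 were lower on the equal-median scale, LYZ (-1.49), MS4A7 (-1.36) and CD68 (-1.03), with camera adjusted p = 0.0108 and adjusted p = 0.157 with an estimated correlation. For the plasma cell list the median was -0.03, the mean 0.20 and the camera direction downward (adjusted p = 0.774), so the measures differ in sign.

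**Figure D3:**
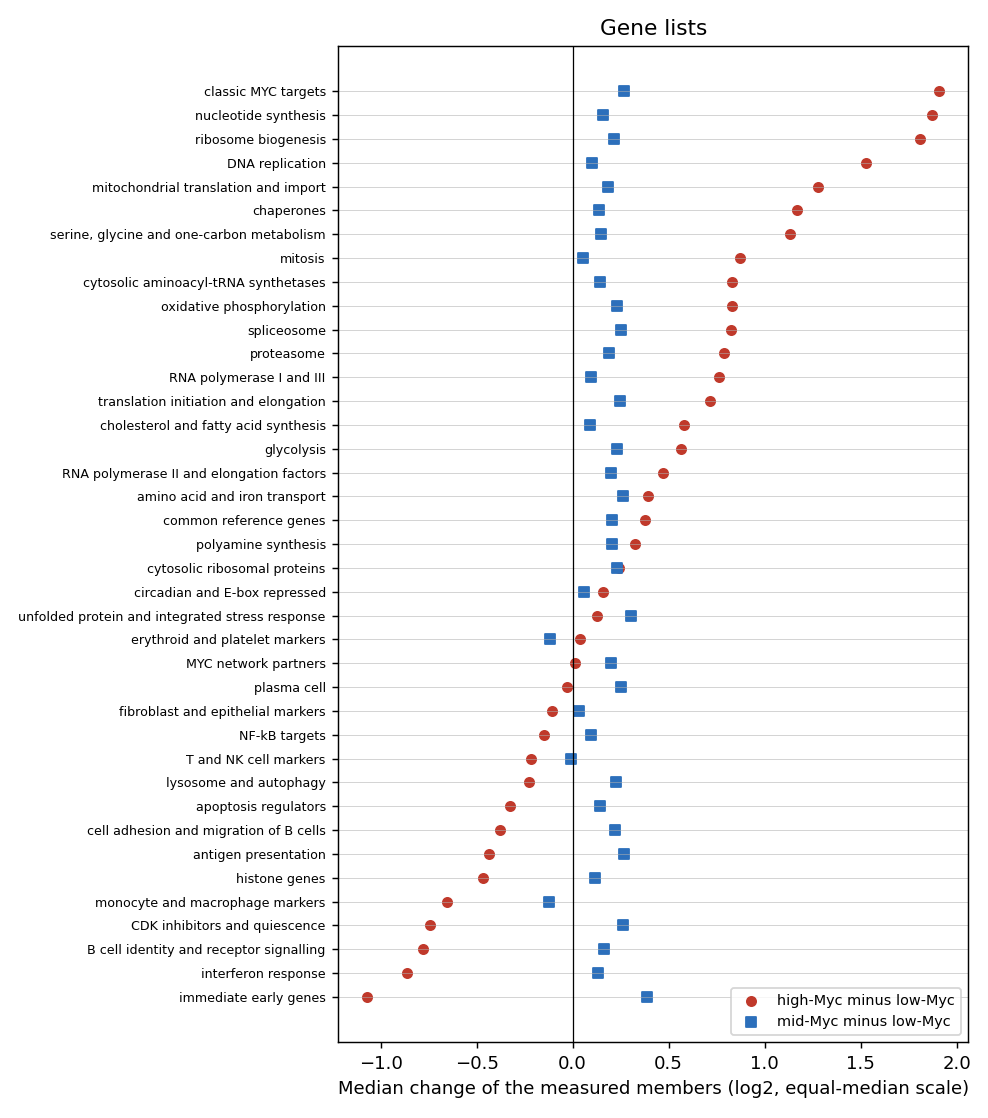
Median change (log2, equal-median scale) of the measured members of each gene list in high-Myc (circles) and mid-Myc (squares) against low-Myc cells. Classic MYC targets lie at 1.91 in high-Myc and 0.27 in mid-Myc cells, and immediate early genes at -1.07 and 0.39.

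After 1 hour of release, the 10 genes with the largest rise per cell included several signalling genes. The pro-apoptotic gene BCL2L11 rose by 2.65 log2 per cell (SE 0.06), TENT5C by 2.28 (SE 0.06), the nuclear receptor NR4A2 by 2.27 (SE 0.12), the cAMP response modulator CREM by 2.26 (SE 0.07) and the cAMP phosphodiesterase PDE4B by 2.16 (SE 0.06). KLHL15, the kinase SIK1, LDLRAD4, the glycolysis regulator PFKFB3 and the clock gene PER1 rose by 1.94, 1.94, 1.87, 1.87 and 1.78, with adjusted p of at most 1.74e-06 for these 10 genes (limma, Benjamini-Hochberg). The falls were smaller, with HPX at -0.79, ZNF425 at -0.77, C8orf44 at -0.70, CSKMT at -0.65, ABCA10 at -0.62, SSTR1 at -0.60, ZNF616 at -0.59, H2AC15 at -0.57, and LOC613206 and CREB3L3 at -0.56 (adjusted p of at most 0.0232). HPX went from 256.4 to 113.3 intensity, and the other 9 lay at 27.8 (SSTR1) to 51.6 (ABCA10) in mid-Myc arrays, around the filter level of 33.8. All 10 lay within the intensity range of the background probe sets. The other probe set of CREB3L3 and 1 of the 2 others of CSKMT had the opposite sign.

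On the per-cell scale 7615 genes were higher, 105 of them by 2-fold or more, and 85 lower at 1 hour. The median gene rose by 0.30 log2, 1.23-fold (1.20 to 1.25 on resampling the ERCC probe sets). The exact permutation test of the array medians gave p = 0.333. The 7 background probe sets above the filter, which were not tested, also lay 0.19 to 0.45 higher per cell, a range that holds this median. As deposited, all 23 lay at 0.006 ± 0.145 (SD) in mid-Myc against low-Myc arrays, so this rise too largely restates the subtracted curve. With arrays centred on an equal median 3139 were higher and 414 lower, but the split rested on the centring: 955 were higher and 1195 lower with quantile normalization, 1527 and 1077 when centred on the tested genes, and 1053 and 1034 with cyclic loess. The share higher among the called was 88.3%, 44.4%, 58.6% and 50.5% in turn, and the median change of all genes was 0.092, -0.022, -0.024 and -0.0098. Of the 414 genes lower on the equal-median scale, 85 were lower per cell and the other 329 were not called. Single arrays moved these counts: without low-Myc replicate 2 there were 1900 higher and 198 lower, and 51 lower per cell, without mid-Myc replicate 2 there were 1951 higher, and without low-Myc replicate 1 and mid-Myc replicate 1 there were 215 and 233 lower.

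Among the lists at 1 hour, immediate early genes and stress response genes stood out. Of 28 immediate early genes, 18 were higher and 2 lower (19 and 3 adjusted over the list alone), with NR4A2 (2.03), EGR3 (1.24), DUSP4 (1.14) and DUSP5 (1.04). Of 24 genes of the unfolded protein and integrated stress response 21 were higher (22 adjusted over the list alone), with HERPUD1 (1.33), ATF3 (1.01) and DDIT4 (0.95), although 1 of the 3 other HERPUD1 probe sets had the opposite sign. Camera gave adjusted p = 4.71e-05 and 1.68e-07, and adjusted p = 0.361 with an estimated correlation for each, and against random lists of the same level each had adjusted p = 0.0078. Camera called 22 lists higher and 1 lower in all (0 with an estimated correlation, where 1 had an unadjusted p under 0.05), but those 2 were the only lists called against level-matched lists. Both kept their direction with quantile normalization, which left 8 of the 24 stress response genes higher, and 14 of the 28 immediate early genes higher and 4 lower.

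At 1 hour 13 of the 39 list medians changed sign between the equal-median scale and the other centrings. Cytosolic ribosomal proteins were higher in 62 of 64 (62 adjusted over the list alone) with a median of 0.23, but in 1 of 64 with quantile normalization, and with cyclic loess 1 was higher, 2 were lower and the median was -0.022. Camera gave them adjusted p = 3.79e-25, and adjusted p = 0.153 with an estimated correlation, and their median was at the 65.7th percentile of level-matched lists. Classic MYC targets were higher in 23 of 32 (23 adjusted over the list alone), with ODC1 (0.61) and NOLC1 (0.57), but with quantile normalization 6 were higher and 2 lower. They had camera adjusted p = 1.62e-06, adjusted p = 0.361 with an estimated correlation and adjusted p = 0.0577 against level-matched lists. DNA replication genes were higher in 9 of 45 and lower in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.868), and their median turned from 0.099 to -0.029 with quantile normalization, -0.016 centred on the tested genes and -0.033 with cyclic loess.

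**Figure D4:**
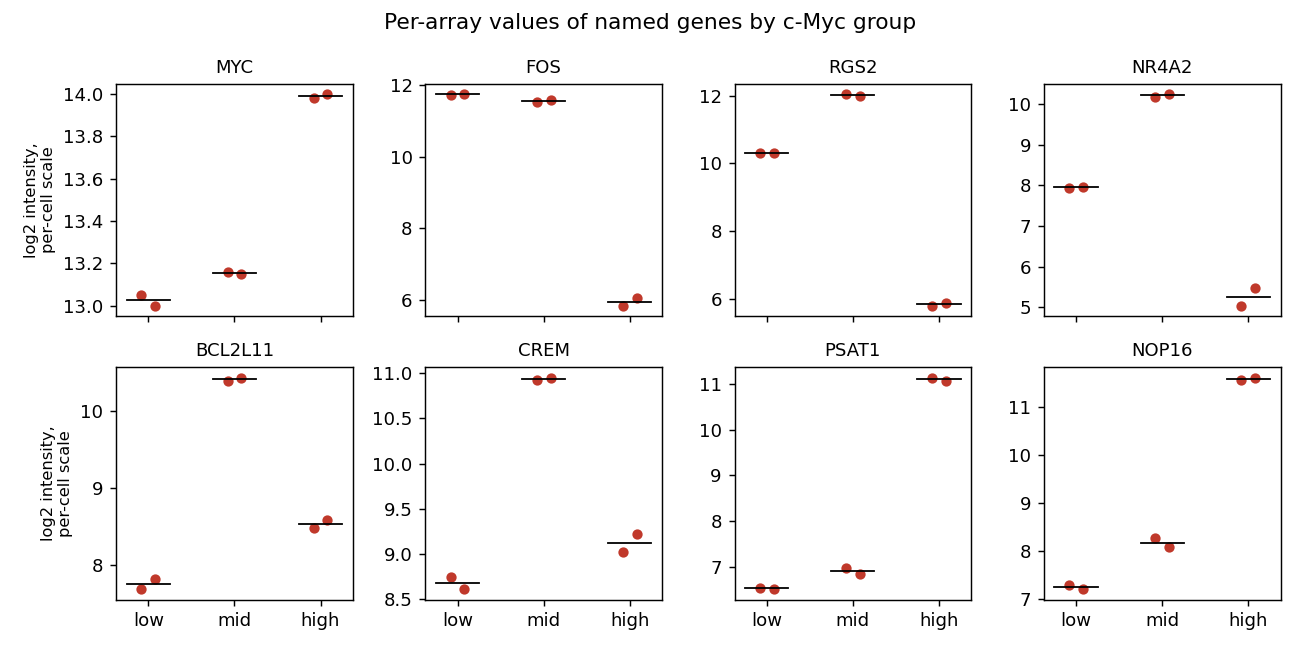
Per-array values (log2 intensity, per-cell scale) of named genes in each group, with points for the 2 arrays and lines for their mean, on axes that do not start at 0. RGS2, NR4A2, BCL2L11 and CREM are highest in mid-Myc arrays, and PSAT1 and NOP16 are highest in high-Myc arrays.

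Between 1 and 24 hours immediate early genes were lower in 24 of 28 on the equal-median scale and higher in 1 (25 and 1 adjusted over the list alone, camera adjusted p = 4.32e-12, and adjusted p = 0.157 with an estimated correlation). Among the named genes, on that list or not, the largest per-cell falls were -6.17 log2 (SE 0.05) for RGS2, -5.62 (SE 0.06) for FOS, -4.96 (SE 0.12) for NR4A2, -4.92 (SE 0.11) for NR4A3 and -4.65 (SE 0.04) for NR4A1. NR4A2 and NR4A3 were at 23.9 and 23.8 intensity in high-Myc arrays, and ADGRA3 at 17.2 in mid-Myc arrays, below the filter level of 33.8, so the sizes of their changes are not settled. Close to that level were RGS2 (35.1) and FOS (38.2) in high-Myc arrays and BZW2 (48.8) in mid-Myc arrays. MTHFD1L rose by 4.51 (SE 0.07), PSAT1 by 4.19 (SE 0.06), ADGRA3 by 4.16 (SE 0.14), BZW2 by 4.14 (SE 0.08) and PUS7 by 4.12 (SE 0.05), and the highest adjusted p of these 10 genes was 2.07e-09 (limma, Benjamini-Hochberg). Ribosome biogenesis genes were higher in 61 of 62 (61 adjusted over the list alone, camera adjusted p = 6.91e-21, and adjusted p = 0.157 with an estimated correlation). All 45 DNA replication genes were higher (45 adjusted over the list alone, camera adjusted p = 2.96e-16, and adjusted p = 0.157 with an estimated correlation). B cell identity genes were lower in 30 of 31 relative to other genes, and adhesion and migration genes in 16 of 21 (30 and 16 adjusted over the list alone), with camera adjusted p = 5.69e-13 and 1.49e-06, and adjusted p = 0.157 with an estimated correlation for each. Per cell, 14 of these B cell identity genes were lower and 8 higher, 6 of the adhesion and migration genes were lower and 8 higher, and 18 of the immediate early genes were lower and 8 higher.

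Per cell 9963 genes were higher and 801 lower between 1 and 24 hours. The median gene rose by 0.72 log2, 1.64-fold (1.59 to 1.69 on resampling the ERCC probe sets). The exact permutation test of the array medians gave p = 0.333. With arrays centred on an equal median 4059 were higher and 3775 lower, and 1924 of those 3775 genes were higher per cell.

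The changes at 1 and 24 hours share the low-Myc arrays, which alone links them. Across genes, which are not independent replicates, they correlated on the per-cell scale at r = 0.199 with a covariance of 0.0362, against r = 0.501 and a covariance of 0.00506 simulated with no change. On the equal-median scale 1650 genes were higher at each time, against 1183 for independent lists, 942 were higher at 1 hour and lower at 24 hours, against 816.3, and 114 were lower at 1 hour and higher at 24 hours, against 156.1. These overlaps were counted under this centring alone. It called 3139 genes higher at 1 hour, against 955 with quantile normalization, 1527 centred on the tested genes and 1053 with cyclic loess. The equal-median correlation was 0.0983 with a covariance of 0.0164, against r = 0.5 and a covariance of 0.00522 simulated with no change, a difference of 0.0112. Part of the excess of genes higher at each time may come from the shared arrays, which are too few to split, whereas shared arrays work against calls in opposite directions.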

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

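The 80th percentile filter, loess span 0.4, loess through the brighter ERCC probe sets, the curve read at each array's own level, centring on the tested genes, cyclic loess, the level-matched lists and the sign of list medians under each centring were chosen after seeing the data. The per-cell medians stayed above 0 under each filter, probe set choice, pseudocount and ERCC curve tried, and turned negative for both comparisons against low-Myc in the values as deposited. With the 80th percentile filter and with every probe set, the number tested differed by construction, and so did the mix of dim and bright ones. How much each moved the counts was not tested, nor was the cause of the other changes below. The signal over background limits dim genes.

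The median per-cell change for high-Myc against low-Myc, mid-Myc against low-Myc and high-Myc against mid-Myc was 0.68, 0.23 and 0.52 with no filter, 1.16, 0.34 and 0.83 with the 60th percentile filter, 1.22, 0.37 and 0.85 with the 80th, 0.90, 0.27 and 0.66 with the mean of all probe sets, 0.85, 0.26 and 0.60 with log2(value + 16), and 1.04, 0.31 and 0.76 with span 0.4. For high-Myc against low-Myc and against mid-Myc it was 0.93 and 0.67 with every probe set, 1.16 and 0.92 with one factor per array, 1.12 and 0.88 with the brighter ERCC curve, and 1.00 and 0.75 with the curve read at each array's own level. In the values as deposited the 3 medians were -0.085, -0.058 and 0.036. Leaving out each array gave 0.95 to 1.01, 0.29 to 0.31 and 0.70 to 0.73.

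Counts per cell, higher and lower in the same order, were 4898 and 180, 4780 and 27, and 4394 and 483 with the 80th percentile filter, 26542 and 754, 17288 and 225, and 23378 and 2009 with every probe set, and 3799 and 4307, 1131 and 1489, and 4144 and 3706 as deposited. Equal-median counts were 2652 and 1792 for high-Myc against low-Myc and 2230 and 2245 against mid-Myc with the 80th percentile filter, with 205 lower at 1 hour, and 10464 and 7737, 6697 and 894, and 9207 and 9264 with every probe set. At 1 hour they were 955 and 1195 with quantile normalization, 1527 and 1077 centred on the tested genes (4931 lower at 24 hours) and 1053 and 1034 with cyclic loess. Leaving out each array moved the 1-hour counts to between 1900 and 3219 higher and 198 and 460 lower on the equal-median scale, and to between 51 and 89 lower per cell, the lowest of each without low-Myc replicate 2. Where 1 array was left, it was assumed to vary like the other groups.

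MYC at 1 hour was 0.13 per cell with no variance trend (adjusted p = 0.0696), -0.055 as deposited, 0.31 with one factor per array (adjusted p = 9.75e-05), 0.17 with the curve read at each array's own level, 0.077 with span 0.4 and 0.076 with the brighter ERCC curve. At 24 hours it was 0.20 as deposited, 1.45 with one factor per array, 0.80 with span 0.4 and 0.79 with the brighter ERCC curve, and when centred on an equal level 0.18 with quantile normalization, 0.14 centred on the tested genes and 0.19 with cyclic loess. When centred on an equal median the 1-hour value was 0.095 with no filter (adjusted p = 0.0844) and with no trend (adjusted p = 0.293), 0.057 with log2(value + 16), -0.15 with quantile normalization, -0.020 centred on the tested genes, -0.16 with cyclic loess, and 0.074 (without low-Myc replicate 2) to 0.12 leaving out arrays. MAD2L1 at 1 hour was -0.051 with the mean of its probe sets (adjusted p = 0.562).

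With an estimated correlation camera called 0 lists in each comparison, while 8 lists had an unadjusted p under 0.05 upward and 4 downward at 24 hours, 1 upward at 1 hour, and 7 and 4 for high-Myc against mid-Myc. The few degrees of freedom of that test leave it little power. Medians of 4, 13 and 2 of the 39 lists changed sign between equal-level centrings. With no filter camera called 0 lists lower at 1 hour (0 at an unadjusted p under 0.05). Quantile normalization left 7 higher at 1 hour, and level-matched lists left 2 higher and 0 lower (10 and 0 unadjusted). Unlike camera, fry does not compare a list with other genes. On the per-cell scale, where 11077 of 12198 genes were higher for high-Myc against low-Myc, it largely follows the common rise. Fry on the per-cell scale called 37 higher and 1 lower, 38 and 0 (0 lower unadjusted), and 32 and 6, and turned these lists upward for high-Myc against low-Myc: CDK inhibitors (adjusted p = 0.000204), histones (0.000383), apoptosis (3.09e-05), B cell identity (0.000279), NF-kB (1.08e-05), interferon (0.00212), antigen presentation (1.78e-05), adhesion (0.000368) and lysosome (6.48e-06); and for high-Myc against mid-Myc: apoptosis (0.000154), NF-kB (8.55e-05), antigen presentation (0.0247) and lysosome (6.63e-05).

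Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated between -0.00895 and 0.0194. With the replicate block, per-cell counts were 11085 and 307 for high-Myc against low-Myc, and 116 list calls kept their side of the threshold while 1 was gained. Over all settings, results on single genes kept their side of the threshold 9393 times, lost their call 168 times and gained one 17 times. In 1 further case the direction changed. The 9393 may include changes of sign in genes called neither in the main setting nor in the alternative.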

Other observations

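The tests on background signal, on replicate differences and on the 2 added gene lists without shared genes were chosen after the results were seen, and those 2 lists were compiled after the genes named at 1 hour had been seen.

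Among genes of the MAX network, which pair with or oppose MYC, 14 of 14 measured members were higher per cell in high-Myc cells, MXD4 by 0.17. Relative to other genes, on the equal-median scale, 6 were higher and 6 lower (6 and 6 adjusted over the list alone), with MXI1 at 1.49 (SE 0.07), MGA at 0.66 and MXD4 at -0.93 (SE 0.07, limma adjusted p = 6.69e-08). Their median there was 0.011 and their mean 0.10, while camera gave a downward direction, and the median turned to -0.19 when centred on the tested genes. Among polyamine genes on that scale, ODC1 and SRM, which make polyamines, were higher by 2.16 and 2.93, and SAT1, which degrades them, was at -3.08. The amino acid transporters SLC7A5 and SLC7A1 were higher by 2.36 and 2.26. Of 12 polyamine genes 7 were higher and 3 lower, and of 16 transport genes 11 and 2 (7 and 3, and 12 and 2, adjusted over the list alone), while per cell 10 polyamine genes were higher and 1 lower, and 15 transport genes were higher. The list tests for these 3 groups gave camera adjusted p = 0.893, 0.56 and 0.0156, and the third had adjusted p = 0.386 with an estimated correlation.

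Genes often used as references were not level per cell, with 15 of 15 higher in high-Myc cells. When centred on an equal median 11 were higher and 3 lower (11 and 3 adjusted over the list alone, median 0.38), with HPRT1 at 1.80 and TFRC at 0.90, and the list test gave camera adjusted p = 0.058. Of 19 histone genes 12 were lower and 3 higher (13 and 3 adjusted over the list alone), on the equal-median scale, with H2BC21 at -2.47 and H2BC5 at -2.22 (camera adjusted p = 0.00136, and adjusted p = 0.172 with an estimated correlation), while per cell 9 were higher and 6 lower.

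The MYC probe set rose by only 0.34 on the equal-median scale, while classic MYC targets rose by a median of 1.91. A candidate explanation is a loss of response at the bright end of the arrays. The spread of changes among the 78 brightest genes was 0.21 of that among genes of middle intensity, where a ratio under 0.5 was predicted, and the brightest ERCC probe sets changed 1.34-fold where those in the middle changed 2.58-fold. Bright genes may also differ less in truth, since many serve every cell, and the true size of the MYC change stays open.

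Most genes rose per cell from low-Myc to high-Myc cells. Random error in cell number or added RNA is argued against by the replicates. Their medians differed by at most 0.026 log2, which is 0.0267 of the median change of the genes. An error shared by both replicates of a group is not tested by this. For the 10297 genes within the range of the background probe sets, non-specific signal cannot be told apart from a true rise. Above 194 intensity that range rests on 1 background probe set, at 694. Above the filter the background probe sets rose 1.1 times as much per cell as human probe sets of their level. As deposited, all 23 lay at 0.01 ± 0.09 (SD), so their per-cell rise largely restates the subtracted curve and the ratio cannot decide. Non-specific signal stays open too for the 1901 genes brighter than every background probe set, whose median rise was 1.05. No background probe set has their level, and the rise of the dimmer ones largely restates the curve, so it gives no bound for them. A biological rise in RNA per cell stays a hypothesis.

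Of the 10 genes named as risen at 1 hour, 10 were lower at 24 hours than at 1 hour on the equal-median scale and 9 per cell, where KLHL15 was higher by 0.28. Their choice by the 1-hour rise favours such a fall, and over all 12198 genes 3775 were lower on the equal-median scale and 801 per cell. Glucocorticoid target genes, listed after the named genes were seen and tested without those named, had a median of 0.43 at 1 hour, at percentile 100 of level-matched random lists (17 genes), and a median at percentile 100 again without immediate early genes and the 4 genes on both lists (13 genes, median 0.32). The corresponding cAMP and CREB list was also at percentile 100 (22 genes, median 0.31), but at 54.65 without immediate early genes and those 4 (9 genes, median 0.13), so its excess lay in the genes left out. A response of glucocorticoid target genes is one possible explanation of part of the pattern, a response to c-Myc is another, and the design holds no release without c-Myc to part them.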
